A study of Homo sapiens with 17 samples.

How the data were processed

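RNA was measured by sequencing in 10 libraries of human head and neck cancer cell lines. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made after removal of ribosomal RNA. Per the submitters' processing notes, the genome build was hg38 and the tools named were CASAVA 1.7, HISAT2 2.1.0, featureCounts 1.6.1 and Picard 2.23.1. The role of each, the gene annotation and the strand and read-pair settings are not given in the sources used here. The authors deposited raw counts of reads per gene, which are whole numbers and were used as deposited. The 7 CUT&Tag samples of the series, which profile H3K27me3, H3K36me2 and an IgG control, were not analysed here.

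The table holds 34496 gene rows, of which 12036 were at 0 in all 10 libraries. A RefSeq gene table of assembly GRCh38.p14 matched 26967 rows by symbol and 482 by an older symbol, and 7047 stayed unmatched. The table gave gene class and chromosome. Total counts per library ran, in units of 1e6, from 11.75 to 15.51 in the 6 DMSO and inhibitor libraries, and from 17.59 to 21.74 in the 4 untreated ones. Intervals on single-library values are exact 95% Poisson intervals, which cover counting error only.

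Samples were grouped by their titles. The main comparisons used 2 libraries each of Cal27 with DMSO, the labelled NSD1 knockout of Cal27 with DMSO, and the labelled knockout with EPZ-6438. They were fitted together in edgeR 4.0.16 (R 4.3.3) with the default low-count filter, which left 13241 genes, TMM scaling, and the quasi-likelihood F test with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. "Rose" and "fell" are used for called genes. Fold changes are given as log2 with the standard error (SE) of the fit. The common biological coefficient of variation was 2.6%. Because no label says whether replicates came from separate cultures, p-values measure only the spread between these samples, which may be technical. The test was run first on simulated counts for the 13241 genes with 200 genes changed: in the knockout contrast it recovered 52% of genes changed 1.25-fold, 76% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, and 7.2% of calls fell among unchanged genes. In the inhibitor contrast the shares were 62%, 64%, 86% and 98%, with 8.8%. Both shares of calls among unchanged genes lay above the threshold of 0.05. The simulation took its spread from these data and changed far fewer genes than were called below, so its shares need not carry over.

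Before the data were examined, 35 gene lists, the tests, a rule for named genes and the alternatives were fixed. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on voom values, with an inter-gene correlation of 0.01, then with the correlation estimated per list, and with fry. Of 31 lists tested, camera called 12 in the knockout contrast, 20 in the inhibitor contrast and 17 for the treated knockout against parental cells. With an estimated correlation the calls came to 1, 2 and 3. That version rests on the 3 residual degrees of freedom of the fit. Several estimates lay below 0.01, such as -0.034 for YAP/TEAD targets in the knockout contrast, so a lost call need not reflect a higher correlation. The test fry, which asks only whether a list's genes move on balance, called 26, 27 and 29. Counts of changed members adjusted over the list alone differed from those over all tested genes by at most 2 per direction. No member of the replication-dependent histone list or of the small structural RNA list was matched to a row, so both were left out.

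The rule for named genes took NSD1; the 8 largest called changes each way among protein-coding genes of at least 5 counts per 1e6 (CPM) whose libraries did not overlap; up to 4 members of each list with the lowest adjusted p; a fixed set of genes of interferon signalling, antigen presentation, PRC2 and the NSD family whatever their p; the 8 genes with the lowest larger p among those called in opposite directions in both contrasts; and the 5 largest changes each way between single libraries among genes with at least 100 counts. Genes named outside the rule are marked. Because both contrasts contain the knockout DMSO libraries, 20 sets of unchanged libraries were simulated to give overlap and correlation from noise alone. Comparisons with 1 library per group have no replicate check and no p-value; they use log2 CPM with a prior count of 2 after TMM scaling over all 10 libraries, and list medians were placed among 10000 random lists matched on mean expression.

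Alternatives were DESeq2 1.42.0 on the genes tested by edgeR (where its own low-count filter removed no gene), DESeq2-type size factors, library size alone, other low-count filters, fits of only 2 groups, a replicate block, a test against a log2 fold of 0.5 (glmTreat), a robust spread estimate, leaving out each library, and adding the untreated pair to the knockout contrast. A fit on protein-coding genes alone was added after seeing the data.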

Results

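The series measured RNA in Cal27, a line of tongue squamous cell carcinoma, with and without a label of NSD1 knockout. NSD1 places methyl groups on lysine 36 of histone H3. The labelled knockout was also cultured with EPZ-6438 (tazemetostat), an inhibitor of EZH2, the enzyme that methylates lysine 27 of the same histone. There were 2 libraries each of Cal27 with DMSO, the labelled knockout with DMSO and the labelled knockout with EPZ-6438. A separate set of untreated libraries held 1 each of Cal27, its labelled knockout, and the head and neck cancer lines SKN3 and BICR78. Total counts, in units of 1e6, were 14.04 and 13.85 for Cal27 with DMSO, 12.85 and 13.74 for the labelled knockout with DMSO, and 11.75 and 15.51 with EPZ-6438. The untreated libraries held 21.74, 21.2, 17.59 and 19.49 in the order named. Per the submitters' processing notes, the genome build was hg38. The p-values below measure only the spread between these samples, which may be technical. A single labelled knockout line was measured, so effects of the clone cannot be separated from those of NSD1. No library of parental cells with EPZ-6438 was analysed here.

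NSD1 mRNA itself was higher, not lower, in the libraries labelled knockout. It stood at 163 ± 1.3 counts per 1e6 (CPM; SD, n = 2) with DMSO against 113 ± 0.6 CPM (SD, n = 2) in Cal27, a log2 change of 0.53 ± 0.04 (SE; edgeR, adjusted p = 4.2e-08). In the untreated pair it was 203 CPM (95% Poisson interval 197 to 209) against 149 CPM (144 to 155). EPZ-6438 left it at 155 ± 7.9 CPM (SD, n = 2; adjusted p = 0.13). Counts per gene do not show whether the transcript is edited, so the counts do not check the label, and every direction below is that of the labelled knockout. Of the related genes, NSD2 and NSD3 rose by 0.38 ± 0.04 and 0.41 ± 0.05 (log2, SE). Neither was higher in the untreated pair, which has no replicates.

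**Figure D1:**
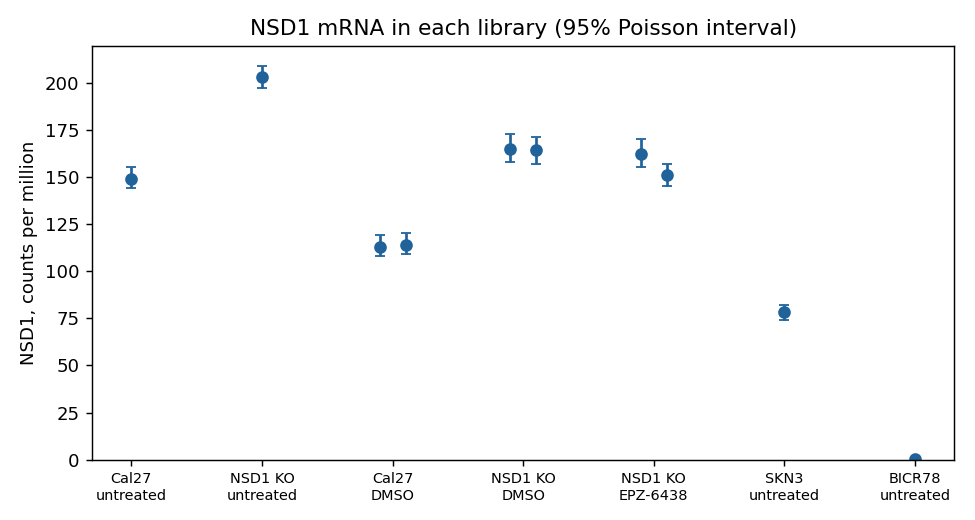
NSD1 in CPM (y axis) in each of the 10 libraries, by group (x axis); points are libraries and bars are 95% Poisson intervals, which cover counting error only. With DMSO, Cal27 lies at 113 and 114 CPM and the labelled knockout at 165 and 164. With EPZ-6438 the labelled knockout lies at 162 and 151. Untreated, Cal27 lies at 149, the labelled knockout at 203, SKN3 at 78.1 and BICR78 at 0.468.

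The first comparison set the labelled knockout against Cal27, both with DMSO. Genes of the interferon response fell in the labelled knockout, as did most genes of keratinocyte differentiation, although only the first list kept its call with an estimated correlation (adjusted p = 0.021 and 0.058). S100A8 and S100A9, which together form calprotectin, fell by 3.37 ± 0.06 and 2.80 ± 0.03 (log2, SE), and the antimicrobial gene S100A7 fell by 4.12 ± 0.09. Keratins of the basal layer fell as well: KRT14 went from 1310 ± 10 to 189 ± 6.8 CPM (SD, n = 2). Among the largest decreases were the nuclear pore gene NUP210 (log2 -6.42 ± 0.24), PPP1R14C, SESN3, the growth factor BMP7, SIRPA, SULF2 and the collagenase MMP13 (log2 -3.93 ± 0.08). The largest increases were the axon guidance ligand SLIT2 (log2 3.21 ± 0.17), MUC2, the cytokine CSF2 (log2 2.25 ± 0.11), ZDHHC2, the cyclin CCND2 (log2 2.04 ± 0.04), VGLL2, VIPR1 and LTBP2.

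In the list of interferon-stimulated genes, 51 of 59 tested members fell and 2 rose (52 and 2 adjusted over the list alone), with a median log2 change of -0.52 (camera, adjusted p = 8.1e-30; adjusted p = 0.021 with an estimated correlation). IFI6 went from 235 ± 5.7 to 28.0 ± 2.3 CPM and MX1 from 406 ± 13 to 143 ± 0.52 CPM (SD, n = 2), and IFI27 fell by 2.15 ± 0.04 (log2, SE). The 2 members that rose were CXCL11 and HERC5, the latter named after its values were seen. ISG15, chosen in the same way, is counted at 1.81 CPM in Cal27 with DMSO against 130 CPM in untreated Cal27, so its value here is not usable. Genes of MHC class I antigen presentation went both ways, with 4 rising and 5 falling of 20 (camera, adjusted p = 0.78). The list median was -0.01, and 0.04 with library size alone. HLA-B and B2M did not pass the test, while TAP1 fell by 0.28 ± 0.04. MHC class II genes fell in 10 of 11 cases, with a median log2 change of -1.90 (camera, adjusted p = 4.5e-09; adjusted p = 0.058 with an estimated correlation). HLA-DRA fell by 1.59 ± 0.05 and HLA-DPA1 by 2.62 ± 0.15. Of the chemokines that attract T cells, CXCL10 fell by 0.95 ± 0.10 while CXCL11 rose by 0.47 ± 0.08, and the list as a whole was not called (camera, adjusted p = 0.34). Checkpoint ligands were not called as a list (median 0.24, mean -0.23; camera, adjusted p = 0.17): CD274, which encodes PD-L1, rose by 0.50 ± 0.11 and LGALS9 fell by 3.56 ± 0.20.

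Of the keratinocyte differentiation list, 16 of 21 members fell and 1 rose, with a median log2 change of -2.74 (camera, adjusted p = 4.6e-10; adjusted p = 0.058 with an estimated correlation). The basal keratinocyte list was mixed, 11 falling and 6 rising of 21 (camera, adjusted p = 0.0021; adjusted p = 0.17 with an estimated correlation), with log2 values of -2.79 for KRT14, -2.28 for KRT15, -2.18 for KRT6A and -1.81 for KRT17. COL17A1, a member named after its values were seen, has the counting limit of ISG15 (28 CPM with DMSO against 1070 CPM in untreated Cal27). It is among the members that did not pass here and among those that fell with EPZ-6438. Targets of the YAP/TEAD transcription factors rose in 9 of 11 cases (camera, adjusted p = 1.8e-09; adjusted p = 0.058 with an estimated correlation), among them CCN1 by 1.08 ± 0.03 and the receptor kinase AXL by 0.99 ± 0.04. Genes induced by MAPK signalling rose in 12 of 14 cases (camera, adjusted p = 1.2e-08; adjusted p = 0.066 with an estimated correlation), FOSL1 by 1.03 ± 0.03. The list of NF-kappaB and inflammatory cytokines had 18 members rising and 5 falling of 26 (camera, adjusted p = 6.8e-06; adjusted p = 0.066 with an estimated correlation). IL1A rose by 1.03 ± 0.02 and CCL20 fell by 1.21 ± 0.06. Of the mesenchymal and matrix list, 13 rose and 7 fell of 25 (camera, adjusted p = 0.009; adjusted p = 0.18 with an estimated correlation), with a median of 0.15 and a mean of -0.22. THBS1 rose by 0.92 ± 0.02.

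Small shifts touched abundant genes. Ribosomal protein genes fell in 26 of 30 cases with a median log2 change of -0.16 (camera, adjusted p = 1.7e-12; adjusted p = 0.24 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases and 1 rose (camera, adjusted p = 1.1e-07; adjusted p = 0.32 with an estimated correlation), and their share of counts was 7.06% and 7.25% in Cal27 against 6.27% and 6.08% in the labelled knockout. The PRC2 list had 3 of 13 members rising (camera, adjusted p = 0.024; adjusted p = 0.24 with an estimated correlation). EZH2 did not pass the test (log2 0.14 ± 0.06). Of markers of other cell types, 3 of 5 immune markers rose (camera, adjusted p = 0.017; adjusted p = 0.23 with an estimated correlation), CD68 and LAPTM5 among them, and 4 of 7 fibroblast markers fell (camera, adjusted p = 0.11).

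In all, 2169 of 13241 tested genes rose and 2580 fell (edgeR, quasi-likelihood, adjusted p below 0.05), of which 181 and 682 changed 2-fold or more. Against a log2 fold of 0.5, 248 rose and 618 fell. With the untreated pair added, 895 rose and 1075 fell. Scaling by library size alone turned the split to 2978 rising and 2088 falling.

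The second comparison asked what EPZ-6438 changed in the labelled knockout. Most interferon-stimulated, MHC class I and MHC class II genes rose. With an estimated correlation the lists stood at adjusted p = 0.010, 0.047 and 0.078, so the MHC class II call was lost. The estimate for MHC class II was -0.069, below the preset 0.01, so a higher correlation does not account for the loss. IFI6 went from 28.0 ± 2.3 to 550 ± 26 CPM, MX1 from 143 ± 0.52 to 907 ± 1.5 CPM, and HLA-B from 368 ± 4.1 to 1230 ± 11 CPM (SD, n = 2 each). S100A9 went from 113 ± 5.5 to 2300 ± 16 CPM (SD, n = 2). The largest increases were DMBT1 (from 0.149 to 38.5 CPM), FCGBP (log2 6.43 ± 0.10), S100A7A, LTF (lactoferrin), the cytokine IL19, S100A7, PIK3AP1 and CD70, a ligand of the TNF family (log2 5.28 ± 0.19). The largest decreases were the EGF-family ligand NRG1, from 268 ± 14 to 35.5 ± 0.32 CPM (SD, n = 2), THBS1 (log2 -2.69 ± 0.02), FST, FGF2, CBLC and RBM24. NME1-NME2 and EIF3CL also stood among them, but the first is a read-through of neighbouring genes and the second has a near-identical copy, so both are uncertain. These 2 and CBLC lost their call with a robust spread estimate.

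Of the interferon-stimulated list, 58 of 59 members rose (58 adjusted over the list alone), with a median log2 change of 1.61 (camera, adjusted p = 1.6e-48; adjusted p = 0.010 with an estimated correlation). IRF1 rose by 0.35 ± 0.04 and MX2 by 3.99 ± 0.05. The counting limit on ISG15 holds here too. All 20 tested genes of MHC class I presentation rose, with a median of 0.42 (camera, adjusted p = 8.8e-15; adjusted p = 0.047 with an estimated correlation), including HLA-C by 1.13, B2M by 0.87 and the peptide transporter TAP1 by 0.88 (log2). MHC class II genes rose in 10 of 11 cases, with a median of 2.44 (camera, adjusted p = 1.8e-07; adjusted p = 0.078 with an estimated correlation). The 5 tested T-cell chemokines rose (camera, adjusted p = 0.00029; adjusted p = 0.11 with an estimated correlation), CXCL10 by 3.02 ± 0.08 and CXCL11 by 1.61 ± 0.07. Of 10 checkpoint ligands, 7 rose and 1 fell (camera, adjusted p = 0.0084; adjusted p = 0.17 with an estimated correlation). The tryptophan-degrading enzyme IDO1 rose by 3.92 ± 0.10, while CD274 did not pass the test (log2 -0.19 ± 0.11).

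**Figure D2:**
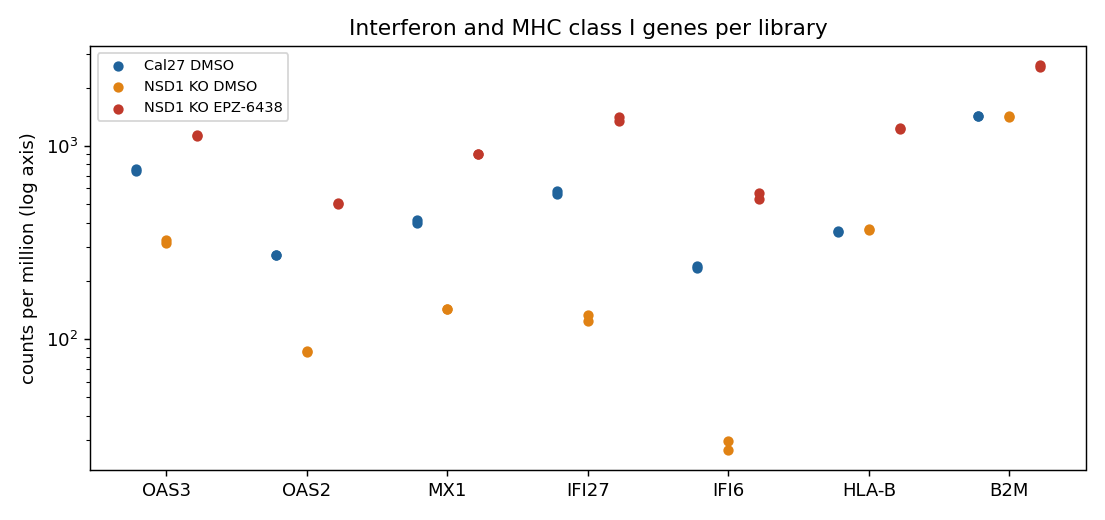
CPM (y axis, log scale) of 7 interferon and MHC class I genes (x axis) in the 6 DMSO and EPZ-6438 libraries; each point is a library, and colours mark the 3 groups. IFI6 stands at 235 CPM in Cal27, 28.0 in the labelled knockout and 550 with EPZ-6438, whereas HLA-B stands at 359, 368 and 1230.

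Keratinocyte differentiation genes rose in 11 of 21 cases and 1 fell (camera, adjusted p = 0.0022; adjusted p = 0.16 with an estimated correlation). The protease inhibitor PI3 rose by 4.77 ± 0.08. Basal keratinocyte genes fell in 13 of 21 cases and rose in 5 (camera, adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation), with KRT5 falling by 1.14 ± 0.02. The NF-kappaB list had 20 of 26 members rising and 3 falling (camera, adjusted p = 9.8e-08; adjusted p = 0.078 with an estimated correlation), PTGS2 by 3.31 ± 0.06. YAP/TEAD targets fell in 5 of 11 cases (camera, adjusted p = 9.8e-05; adjusted p = 0.095 with an estimated correlation), F3 by 0.99 ± 0.03. Cell cycle genes fell in 22 of 30 cases and 2 rose, with a median of -0.17 (camera, adjusted p = 1.4e-05; adjusted p = 0.082 with an estimated correlation), PLK1 by 0.53 ± 0.04, and the cell cycle inhibitor CDKN1A (p21) rose by 0.98 ± 0.07. MAPK-induced genes went both ways, 5 rising and 4 falling of 14 (camera, adjusted p = 0.87), as did mesenchymal and matrix genes, 12 rising and 10 falling of 25 (camera, adjusted p = 0.64). Ribosomal protein genes fell in 23 of 30 cases and 1 rose (camera, adjusted p = 9.8e-08; adjusted p = 0.26 with an estimated correlation) and mitochondrially encoded genes in 10 of 13 (camera, adjusted p = 0.0002; adjusted p = 0.42 with an estimated correlation). Markers of fibroblasts rose in 5 of 7 cases (camera, adjusted p = 0.03; adjusted p = 0.26 with an estimated correlation) and immune markers in 4 of 5 (camera, adjusted p = 0.016; adjusted p = 0.18 with an estimated correlation), CD14 by 1.78 ± 0.10. Of the PRC2 subunits, EZH2, EED, SUZ12 and EZH1 did not pass the test.

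**Figure D3:**
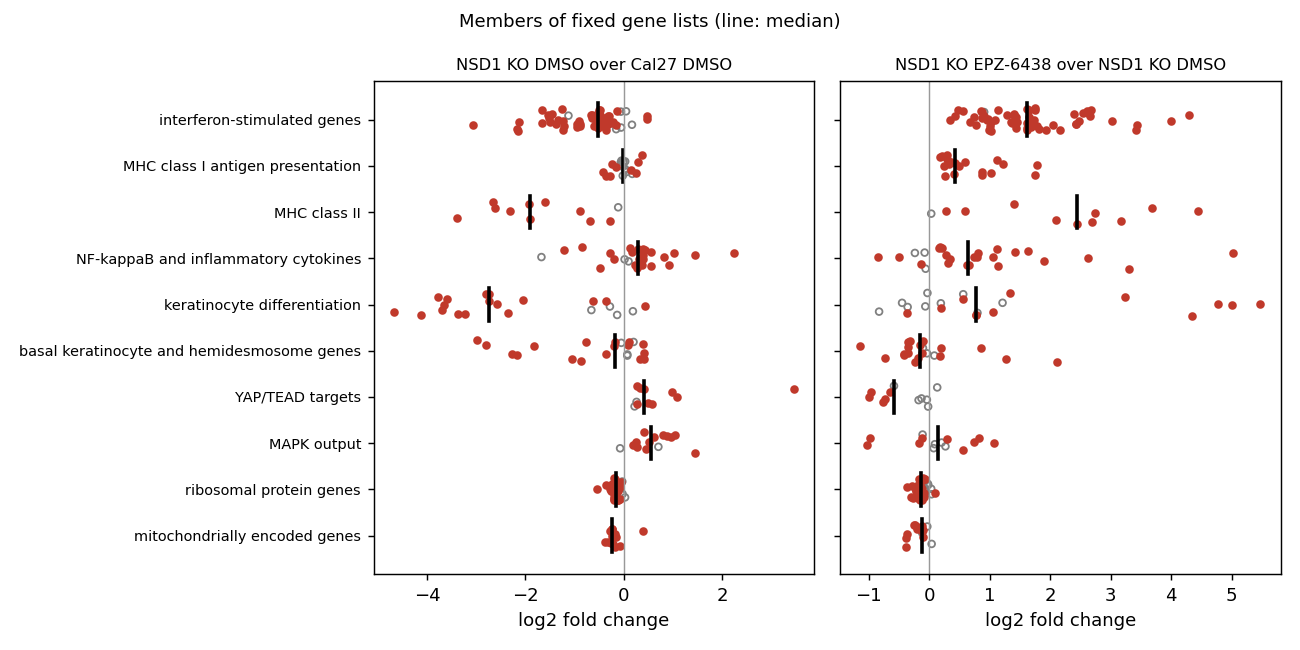
Log2 fold change (x axis) of each tested member of 10 fixed lists (y axis) in the knockout contrast (left) and the inhibitor contrast (right); filled points passed the test at an adjusted p below 0.05, open ones did not, and black lines are medians. The interferon median lies at -0.52 on the left and 1.61 on the right, and the MHC class I median at -0.01 and 0.42.

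Of 13241 genes, 3393 rose with EPZ-6438 and 3171 fell (edgeR, quasi-likelihood, adjusted p below 0.05), 1199 and 120 of them by 2-fold or more. Against a log2 fold of 0.5, 1272 rose and 204 fell.

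The third comparison asked which changes of the labelled knockout EPZ-6438 moved the other way. The genes that fell in the knockout contrast and rose with the inhibitor were led by OAS3, OAS2, MX1, IFI27, IFI6, S100A9, S100A8 and S100A7. The opposite set, higher in the labelled knockout and lower with the inhibitor, was led by THBS1, FGF2, PHLDA1, CCND2, FOSL1, AXL, the death receptor TNFRSF21 and CCN1. Interferon-stimulated genes gave 51 of 59 members to the first set where 5.5 were expected (one-sided Fisher's exact test, adjusted p = 7.3e-43), MHC class II 10 of 11 (1.5e-08), keratinocyte differentiation 9 of 21 (0.0011) and hypoxia and glycolysis 7 of 20 (0.016). The second set held 8 of 25 mesenchymal and matrix genes (0.0015), 5 of 11 YAP/TEAD targets (0.004) and 7 of 30 cell cycle genes (0.019). Genes are not independent, so these p-values are too small. For the interferon and MHC class II lists most of the overlap was also fixed by the earlier list results. Of the interferon-stimulated genes 51 of 59 fell in the knockout contrast and 58 rose with EPZ-6438. MHC class II genes did so in 10 of 11 cases each. Their p-values here add no separate evidence. Those of the other lists also repeat in part how many members changed in each contrast. Of hypoxia and glycolysis genes, 9 of 20 fell in the knockout contrast and 14 rose with EPZ-6438. Of cell cycle genes, 9 of 30 rose and 22 fell. Neither list was called in the knockout contrast (camera, adjusted p = 0.13 and 0.091). Overlap beyond such counts was not tested.

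The first set numbered 1235 genes and the second 831, against 661 and 519 for independent lists. Simulated unchanged libraries gave 0.65 and 0.8. Without changed genes almost nothing is called, so these low values were fixed in advance. They do not show how much overlap the shared libraries add when many genes change, which was not simulated. Another 471 genes were higher in both contrasts (556 for independent lists) and 507 lower in both (618). DESeq2 gave 798 and 500, a log2 fold of 0.5 gave 365 and 31, and without replicate 1 or replicate 2 of the labelled knockout with DMSO the second set held 550 or 542. Library size alone turned the order of the sets, with 1100 genes in the first and 1147 in the second. Across genes, which are not independent replicates, the log2 changes of the contrasts correlated at -0.558 (Spearman -0.333) against -0.50 in simulated unchanged libraries. Noise in the shared libraries gives about -0.50 whatever its size, so that value does not measure their part in -0.558. The covariance does depend on the size of the noise, and was -0.369 against -0.0208 simulated, a difference of -0.348. The contrasts share the knockout DMSO libraries, which cannot be divided into 2 groups of 2, so part of the excess overlap may come from them.

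**Figure D4:**
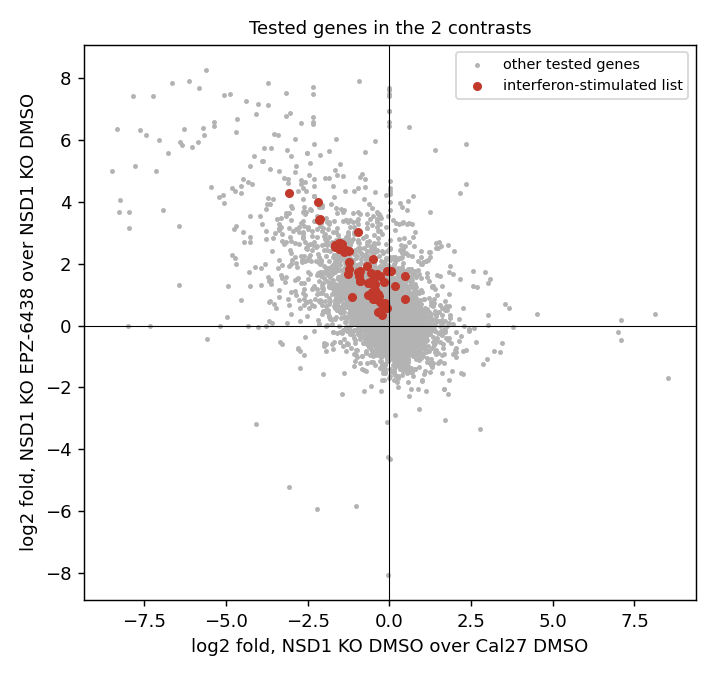
Log2 fold change of 13241 tested genes in the knockout contrast (x axis) and the inhibitor contrast (y axis), with the 59 interferon-stimulated genes in red. Of these, 51 fell on the x axis and rose on the y axis. The axes share the 2 knockout DMSO libraries, and noise alone then gives a correlation near -0.50 whatever its size. The covariance was -0.369, against -0.0208 in simulated unchanged libraries.

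Set directly against Cal27 with DMSO, the labelled knockout with EPZ-6438 stood above the parental level for most interferon genes. Of the interferon-stimulated list, 56 of 59 were higher with a median of 0.89 (camera, adjusted p = 7.7e-34; adjusted p = 0.018 with an estimated correlation), and 19 of 20 MHC class I genes were higher with a median of 0.55 (camera, adjusted p = 3.2e-14; adjusted p = 0.034 with an estimated correlation). IFI27 was 1.26 ± 0.03 above Cal27 and HLA-B 1.78 ± 0.03 (log2, SE). NF-kappaB genes were higher in 24 of 26 cases (camera, adjusted p = 5.3e-16; adjusted p = 0.034 with an estimated correlation). The basal keratins KRT14 and KRT5 were low, at -3.52 ± 0.03 and -2.20 ± 0.02, while the simple epithelial keratins KRT7 and KRT18 were higher, at 1.18 ± 0.12 and 0.41 ± 0.03. Keratinocyte differentiation genes were mostly still below Cal27, 12 lower and 5 higher of 21 with a median of -1.0 (camera, adjusted p = 0.41). Ribosomal protein genes were lower in 28 of 30 cases with a median of -0.31 (camera, adjusted p = 3.8e-16; adjusted p = 0.16 with an estimated correlation), and mitochondrially encoded genes in 12 of 13 with a median of -0.39 (camera, adjusted p = 3e-09; adjusted p = 0.27 with an estimated correlation). Of the immune markers, 4 of 5 were higher with a median of 1.74 (camera, adjusted p = 0.00064; adjusted p = 0.14 with an estimated correlation). In total 3456 genes were higher and 3428 lower. Against a log2 fold of 0.5 these were 1053 and 424, and with library size alone 4016 and 2815. Of the 1235 genes that fell and rose again, 474 ended above Cal27, 172 below, and 589 did not pass the test against it. Of the 831 in the opposite set, 134 ended above, 220 below and 477 did not pass.

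The untreated pair, which shares no library with either contrast, has 1 library per group and no replicate check. Interferon-stimulated genes were again lower in the labelled knockout, in 48 of 59 cases with a median log2 of -0.71, below all 10000 matched random lists. IFI6 was at -3.45 and IFI27 at -2.88. MHC class I genes were higher in 19 of 20 cases with a median of 0.45, HLA-B at 1.82. Keratinocyte differentiation genes were lower in 21 of 22 cases, with a median of -2.78, and KRT14 was at -7.21. NF-kappaB genes were higher in 25 of 25, with a median of 1.72. Ribosomal protein genes were lower in 30 of 30 cases with a median of -0.24, and mitochondrially encoded genes in 12 of 13 with a median of -0.40. The 5 immune markers considered were higher in 5 of 5 cases with a median of 1.15, but over all listed members the median was 0. By size, MUC6 (265 counts against 0), C15orf48 (3018 against 28), CSF2 (929 against 19) and CCND2 (2138 against 48) led the increases, and SPRR1B (2 against 2590), PKP1 (32 against 14022), SPRR1A (0 against 1053), BMP7 (1 against 1173) and KRT4 (4 against 1844) the decreases. BIVM-ERCC5, a read-through, is uncertain. KRT4 and SPRR1A stood at 87.7 and 50.1 CPM in untreated Cal27 but at 0.444 and 2.29 CPM in Cal27 with DMSO, so their decrease here depends on the set. Of genes that fell in the DMSO contrast, 77.6% (95% Wilson interval 75.9 to 79.1) were lower here, and of those that rose, 76.1% (74.3 to 77.9) were higher. Wilson intervals here and below treat genes as independent and do not cover variation between libraries, so they are too narrow. The inhibitor response as a whole was not mirrored: 50.8% of genes that rose with EPZ-6438 were lower in the untreated labelled knockout (49.2 to 52.5), against 50.7% of all tested genes, and 44.8% of those that fell were higher (43.1 to 46.5), against 49.3%. Of the 1235 genes that fell and rose again, 76% were lower here (73.5 to 78.3), and of the 831 in the opposite set 67.6% were higher (64.4 to 70.7), no larger shares than those of the knockout calls as a whole. These shares follow the knockout contrast and do not test the response to the inhibitor. Across genes the inhibitor contrast and the untreated pair correlated at -0.183 (Spearman -0.032), and the knockout contrast and the untreated pair at 0.513 (Spearman 0.421). With library size alone as scaling, the 2 inhibitor shares became 44.7% and 60.2%. That scaling also moved the median of all tested genes in the pair from -0.01 to 0.09. The shares of all tested genes were not computed under it, so these 2 shares cannot be set against 50.7% and 49.3%.

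SKN3 and BICR78, with 1 library each, had lower interferon-stimulated genes than untreated Cal27, in 57 and 55 of 59 cases with median log2 values of -2.79 and -1.22, each below all 10000 matched random lists. MHC class I genes were lower too, with medians of -1.10 and -0.78. TGF-beta targets had a median of 1.57 in both lines, and the 25 NF-kappaB genes considered were at -1.71 in BICR78 and -0.94 in SKN3. The SKN3 median had a 95% interval of -1.32 to 0.01, and over all listed members it was -0.29, or -0.13 with library size alone. Mitochondrially encoded genes had a median of -0.92 in SKN3 and 0.51 in BICR78, where they took 12.14% of counts against 7.48% in Cal27. Of 5 immune markers considered, 5 were lower in SKN3 with a median of -2.91, and 4 in BICR78 with a median of -0.59. Over all listed immune markers the median was 0 in both lines. NSD1 was at 78.1 CPM in SKN3 (95% Poisson interval 74.2 to 82.2) and at 0.468 CPM in BICR78 (9 counts; 0.214 to 0.888), against 149 CPM in Cal27. SKN3 was highest over Cal27 for COL5A2 (13574 counts against 17), the glucose transporter SLC2A3 (5334 against 6), INHBE and SLC20A2, and lowest for THBD (0 against 2100), RAC2, MAGEA4, MAGEA6 and EDIL3. LGALS7, which has a near-identical copy, is uncertain. BICR78 was highest for ALPG (11281 against 9), PEG10, KRT19 (32497 against 54), MXRA8 and TUSC3, and lowest for CXCL1 (1 against 1783), PLAA and the cancer-testis genes MAGEA3, MAGEA4 and MAGEA6.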

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

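In this part, the tests of a label exchange, of the sets' counting and growth, of chromosome 4 copies shared by both sets and of a few strong genes were chosen after the result was seen; those of the NSD1 region, gene overlap, expression level and other splits were chosen before.

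Some results went one way in the replicated DMSO libraries and the other way in the untreated pair; the difference between the sets was not tested. MHC class II genes had a median log2 of -1.90 with DMSO and 0.22 in the untreated pair (0.13 over all listed members). MAPK-induced genes had a median of 0.56 with DMSO and -0.04 in the untreated pair. Over all listed members the untreated median was -0.07, and 0.03 with library size alone. Lists not called with DMSO also differed between the sets. MHC class I genes had a median of -0.01 with DMSO and 0.45 in the untreated pair, where 19 of 20 were higher. T-cell chemokines had a median of -0.31 with DMSO and 0.65 in the untreated pair, with 3 higher and 2 lower. Among named genes, 29 of the 139 that passed the test with DMSO had the opposite sign in the untreated pair. Those at least 2-fold changed in both were LTBP2 and PECAM1. LTBP2 was at 1.83 with DMSO and -1.14 untreated. PECAM1 was at -1.68 with DMSO and 1.84 untreated, the last from 7 counts against 0. Smaller reversals included CXCL10 (-0.95 with DMSO and 0.65 untreated), HLA-DRA (-1.59 and 0.69), TAP1 (-0.28 and 0.63), PHLDA1 (0.96 and -0.39), NSD2 (0.38 and -0.05) and NSD3 (0.41 and -0.20).

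NSD1 mRNA was higher in the libraries labelled knockout. An exchange of labels in only one of the 2 sets is argued against by the correlation of 0.513 across all tested genes between the knockout over parental changes of the sets, where an exchange would give a negative one. Over the 12894 tested genes placed on chromosomes 1 to 22 and X the correlation was 0.549 (95% interval 0.512 to 0.586 over resampled chromosomes). Extra copies of the NSD1 region are argued against by the 20 nearest tested genes, whose median log2 was -0.05 against 0.53 for NSD1. An exchange in both sets cannot be told apart from correct labels, because the counts do not show which transcripts are edited, and an edit that leaves the mRNA in place may give the same rise of 0.53; both stay open.

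A group of abundant genes was far lower in the DMSO and EPZ-6438 libraries than in the untreated ones. Examples, named after their values were seen, are NOTCH1 (269 CPM in untreated Cal27 and 1.26 with DMSO; 0.193 in the labelled knockout with EPZ-6438), COX6B1 (172, 1.52 and 0.674), RPS27 (420, 6.4 and 6.09) and GSTP1 (1550, 25.9 and 26.8). Of 35 genes at least 16-fold lower in Cal27 with DMSO than untreated, 85.7% were at least 8-fold lower in the labelled knockout too. Reads assigned to genes differently in the 2 sets would give such a share. Exceptions, named after their values were seen, included KRT4 (log2 -7.28 in Cal27, -1.31 in the labelled knockout), KRT13 (-5.03, 0.29), SLURP2 (-4.71, 1.96) and SPRR1A (-4.41, 2). KRT4 and SPRR1A had 4 and 0 counts in the untreated labelled knockout, so no fall could show there. A difference of the Cal27 cells between the sets was not tested for these genes. Different growth is argued against as the cause for the ribosomal genes: RPS27 was -6.01 while the ribosomal protein list had a median of 0.27 (log2). Overlap with another gene of the reference table was not decided by the odds ratio of 0.878 (95% interval 0.37 to 2.14). Of the fixed lists' members, ISG15 and COL17A1 were among the genes lower in both Cal27 and the labelled knockout, and smaller differences were not searched for. Apart from such checks of the sets themselves, levels were therefore compared only within a set.

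Genes of chromosome 4 were higher in the labelled knockout with DMSO, with a median log2 of 0.212 over 465 genes against at most 0.131 for any other chromosome. A few strong genes are argued against by the 74.2% of its genes above 0, and expression level by a median above 100% of 10000 matched gene sets, whose highest was 0.038. A copy number difference present in both sets is not decided by the untreated pair, which has no replicates. There chromosome 4 was at 0.053, below its 0.212 with DMSO but with 57.8% of its genes above 0. The other chromosomes ranged from -0.228 to 0.089. Chromosome 21 was the highest of these in both sets, at 0.131 with DMSO and 0.089 untreated. Of its genes, 64% and 61.6% lay above 0. Chromosomes 2 and 8 were shifted in that pair, at -0.228 and -0.17, against -0.042 and 0.014 with DMSO. The cause of those shifts was not tested. A copy number difference, in both sets or with DMSO alone, may remain, as a hypothesis that RNA counts do not test. How far the chromosome 4 shift enters the results for lists and single genes with DMSO was not examined.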

How the results depend on the processing

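Of the alternatives, the protein-coding fit was chosen after seeing the data. Counts of calls stayed within 1.5 times of the reported values in all fits except these, where the cause lies in the stricter test, the fewer libraries or was not tested. Against a log2 fold of 0.5, the knockout contrast gave 248 genes higher and 618 lower, the inhibitor contrast 1272 and 204, the treated knockout against parental 1053 and 424, and the opposite-direction sets 365 and 31. DESeq2 gave 798 and 500 for those sets; the cause was not tested. Adding the untreated pair gave 895 higher and 1075 lower in the knockout contrast, of which 885 and 1060 were called with the same sign before; the 10 splits of these 6 libraries are too few for a share under 0.05 (1970 genes for the real split, at most 0 for the others, so 1 split as large). Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 542 to 785 genes higher in the labelled knockout and lower with EPZ-6438. MHC class I genes in the knockout contrast passed in fry (adjusted p = 0.0317), which does not compare them with other genes; over the other alternatives the adjusted p was 0.682 to 0.923. Library size alone gave 1100 and 1147 genes in the opposite-direction sets, within 1.5 times but in the other order. The shares of the untreated check moved with library size alone, to 44.7% and 60.2%, since that scaling shifts the median of all genes in the pair from -0.01 to 0.09; in SKN3 it shifts from -0.13 to 0.02. The replicate numbers do not pair the samples (correlations of deviations 0.024, -0.034 and -0.016 between groups); with a replicate block the knockout contrast gave 2054 and 2458 genes, the inhibitor contrast 3299 and 3071, and the opposite-direction sets 1164 and 769. Of 283 called results for named genes, 169 kept call and sign in all 16 fits, 114 lost the call in at least 1, mostly (109) against a log2 fold of 0.5, and 0 reversed. With 2 libraries per group of 11.75 to 15.51 (1e6) counts, genes of few counts such as PECAM1 or VWF rest on wide errors.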

Other observations

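No test in this part was chosen after its result was seen. Genes of further lists moved with EPZ-6438. HOX genes, which Polycomb proteins hold silent in many cells, rose in 13 of 29 cases and 1 fell (camera, adjusted p = 0.037; adjusted p = 0.18 with an estimated correlation), HOXC10 by 1.24 ± 0.18 (log2, SE) and HOXD1 from 0.149 to 1.27 CPM. Other developmental transcription factors went both ways, 13 rising and 3 falling of 42 (median -0.03, mean 0.38; adjusted p = 0.64), with FOXA1 rising by 1.72 ± 0.13. Hypoxia and glycolysis genes rose in 14 of 20 cases and 2 fell (adjusted p = 1.1e-05; adjusted p = 0.089 with an estimated correlation), CA9 by 0.79 ± 0.05. NDRG1, which fell by 3.29 ± 0.04 in the knockout contrast, rose by 1.54 ± 0.05. TGF-beta targets rose in 7 of 12 cases (adjusted p = 0.0055; adjusted p = 0.17 with an estimated correlation), PMEPA1 by 1.43 ± 0.06. Simple epithelial genes rose in 6 of 10 cases and 1 fell (adjusted p = 0.0055; adjusted p = 0.26 with an estimated correlation), MUC1 by 1.76 ± 0.07 and ELF3 by 1.86 ± 0.07. Interferon receptor and nucleic acid sensing genes rose in 7 of 15 cases and 2 fell (adjusted p = 0.025; adjusted p = 0.4 with an estimated correlation), and cholesterol synthesis genes fell in 12 of 21 and 4 rose (adjusted p = 0.037; adjusted p = 0.18 with an estimated correlation), SQLE by 0.48 ± 0.05. The lists of p53 targets, NRF2 targets, amino acid stress, WNT, immediate-early genes, CDK inhibitors, and H3K36 and PRC2 enzymes were not called with EPZ-6438 (adjusted p from 0.32 to 0.87); SLC7A11 fell by 1.49 ± 0.07 and PSAT1 by 0.92 ± 0.03. Of 4 cancer-testis and 3 endothelial genes tested, too few for a list test, MAGEA4 rose by 0.09 ± 0.03 and PECAM1 went from 0.221 to 2.41 CPM. For NRF2 targets the median was -0.02 and the mean 0.28, and for WNT genes 0.06 and 0.45, while camera pointed down for both.

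In the knockout contrast, these lists were not called: developmental transcription factors had 12 of 42 falling and 3 rising (adjusted p = 0.15), HOX genes 4 falling and 2 rising of 29 (0.69), H3K36 enzymes 4 rising and 1 falling of 12 (0.051), cholesterol synthesis 8 falling and 3 rising of 21 (0.085), hypoxia and glycolysis 9 falling and 4 rising of 20 (0.13), cell cycle 9 rising and 3 falling of 30 (0.091), p53 targets 8 rising and 5 falling of 18 (0.34), NRF2 targets 8 falling and 3 rising of 19 (0.38), WNT 5 falling and 4 rising of 12 (0.75), TGF-beta targets 5 rising and 4 falling of 12 (0.94), simple epithelial genes 5 rising and 4 falling of 10 (0.62), immediate-early genes 6 falling and 1 rising of 13 (0.11), amino acid stress 3 falling and 1 rising of 17 (0.58), CDK inhibitors 1 falling and 0 rising of 6 (0.78) and interferon receptors 3 rising and 2 falling of 15 (0.96). Median and mean differed in sign for simple epithelial genes (0.08 and -0.29), p53 targets (0.15 and -0.03) and CDK inhibitors (0.02 and -0.06). Library size alone turned the medians of interferon receptors and HOX genes from -0.01 to 0.04, and that of hypoxia genes from -0.05 to 0. The thyroid factor FOXE1 fell by 2.31 ± 0.20 and WNT5A by 3.03 ± 0.35.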
